A study of Homo sapiens with 4 samples.

How the data were processed

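The data were 4 ChIP-seq libraries from EPC2 cells, 1 per group, with STAT6 after 30 min of vehicle or IL-13 (100 ng/mL) and H3K4me3 after 4 h of vehicle or IL-13. Per the labels' protocols, chromatin was sheared by sonication, and 25 µg of chromatin went into each STAT6 and 5 µg into each H3K4me3 immunoprecipitation. The protocol text gives the IL-13 dose for the 30 min STAT6 experiment, and the dose at 4 h is not given in the sources used here. The sample labels list RNA as the molecule, although the antibodies, the protocols and the files are those of ChIP-seq.

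Per the submitters' processing notes the genome build was GRCh37. The aligner is not given in the sources used here. Per the file headers, peaks were called in each library separately with MACS, version 2.1.0.20150731 for STAT6 and 2.1.0.20140616 for H3K4me3, without a control library and with a single genome-wide background in place of a local one, at a q-value cutoff of 0.05 and with summits split within peaks. The headers give 75 bp tags and estimated fragment lengths of 147 bp for both STAT6 libraries, 153 bp for H3K4me3 after vehicle and 152 bp for H3K4me3 after IL-13. After duplicates above the caller's limit were removed, 5377373 tags remained for STAT6 after vehicle, 7631167 for STAT6 after IL-13, 6851995 for H3K4me3 after vehicle and 7545300 for H3K4me3 after IL-13, with redundant rates of 9, 7, 3 and 4%. With no control and no local background, the call amounts to a constant tag height per library, so regions with many tags for any reason were called, and a deeper library could call regions of lower enrichment. The lowest summit called was 5 tags in STAT6 after vehicle, 6 tags in STAT6 after IL-13 and 4 tags in both H3K4me3 libraries.

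The deposited signal of a summit is its pileup, a whole number of overlapping extended tags that the authors' caller did not scale for depth. The deposited fold enrichment, a ratio, equalled the pileup plus 1 over the background height plus 1 within 2e-05 in each list. The deposited −log10 p-values and −log10 q-values are those of the authors' caller. Fold enrichments and q-values are the peaks' own values from the authors and were used only to rank or filter regions within a list. Heights of different lists were set side by side as tag counts, or in the closing section divided by the library's filtered tags, with the library totals above. The narrowPeak and summit tables repeat the same peaks and were not used.

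Lines with the same start and end are summits of the same region, so each distinct interval was counted once, with the values of its highest summit. The STAT6 lists held 583 and 1435 summit lines and the H3K4me3 lists 42369 and 45505, for vehicle and IL-13. A region was shared when it overlapped a region of the other treatment by at least 1 bp, and otherwise called in that treatment only. Such a call means that the other library did not reach its own threshold there, not that the signal was absent. Shares are given with Wilson 95% intervals, which cover counting error only. These intervals, and the counting SDs given below, treat regions as independent, so they are too narrow where called regions lie in groups. Random positions kept each region's width and chromosome, were drawn 100 times between the chromosome's start and the last called position, and did not avoid assembly gaps. Distances run between the nearest ends. Before the data were examined, the regions to be named were fixed as the 10 IL-13-only and 5 vehicle-only STAT6 peaks and the 10 IL-13-only and 10 vehicle-only H3K4me3 peaks with the highest fold enrichment, ties included, together with peaks at ANO1, SOCS1, CISH, CCL26 and CAPN14. For H3K4me3 the rule had been written for promoters and was applied to regions. The gene table used, RefSeq on GRCh38, is of another build than the peaks, so it served only for the chromosome of ANO1. Peaks at the named genes, distances to transcription starts, promoters, gene lists and the STAT6 sequence motif were not analysed here, since no genome or annotation of GRCh37 was used.

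Alternatives fixed before the data were examined were a −log10 q-value of at least 5 in both lists or in the counted list, a reciprocal overlap of at least 50%, and a gap of up to 1 kb counted as shared. Chosen after seeing the data were counting each summit line, leaving out regions within 100 kb of a vehicle STAT6 region, thinning the IL-13 heights to the vehicle depth, and the settings of the H3K4me3 regions near STAT6. Thinning drew each IL-13 summit height binomially and applied the vehicle library's lowest called height, and did not redo the caller's minimum length. For missed regions at equal rates, each IL-13 summit height was scaled by the ratio of filtered tags, and the Poisson chance of falling below the lowest vehicle summit was summed. No p-values were computed, because each group had 1 library. The overlap and distance code was tested on simulated regions, where 226 and 10124 planted overlaps were recovered at 100% in the STAT6 and H3K4me3 comparisons, and its shared counts equalled those of bedtools 2.31.1 in all 4 lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.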

Results

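EPC2 cells, telomerase-immortalized human esophageal keratinocytes, were grown for 5 days at an air-liquid interface, a culture in which keratinocytes stratify, and were exposed to the type 2 cytokine interleukin 13 (IL-13) or to vehicle. Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out for STAT6, the transcription factor that the IL-13 receptor activates, after 30 min, and for trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active promoters, after 4 h. Each of the 4 groups held 1 library. The libraries held 5939620 tags for STAT6 after vehicle, 8176546 for STAT6 after IL-13, 7083487 for H3K4me3 after vehicle and 7863799 for H3K4me3 after IL-13. With no replicate libraries, no difference between treatments below has a replicate check, and no p-value is given. The intervals are Wilson 95% intervals, cover counting error only and treat regions as independent, although many lie in groups. The series asks about ANO1, the calcium-activated chloride channel anoctamin 1, in eosinophilic esophagitis, a disease in which IL-13 acts on the esophageal epithelium. Positions are on GRCh37, and no gene annotation of that build was used here, so regions are given by position and were not assigned to genes, exons or introns.

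The first comparison asked where STAT6 was called on chromatin after 30 min of IL-13. The IL-13 library had 1228 STAT6 regions and the vehicle library 452. Of the IL-13 regions, 860 (70.0%, interval 67.4 to 72.5%) overlapped no vehicle region, whereas 83 of the vehicle regions (18.4%, 15.1 to 22.2%) overlapped no IL-13 region. The IL-13-only regions had a median width of 254 bp and a median fold enrichment over the authors' genome-wide background of 6.77. A total of 750 of them (87.2%) were more than 100 kb from any vehicle STAT6 region. The IL-13 library had 1.42 times as many tags after filtering as the vehicle library. Among the 349 IL-13 regions whose height would still be at least 10 tags at the vehicle depth, 100 were not called after vehicle, against 1.39 that Poisson counting would miss at equal tag rates.

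**Figure D1:**
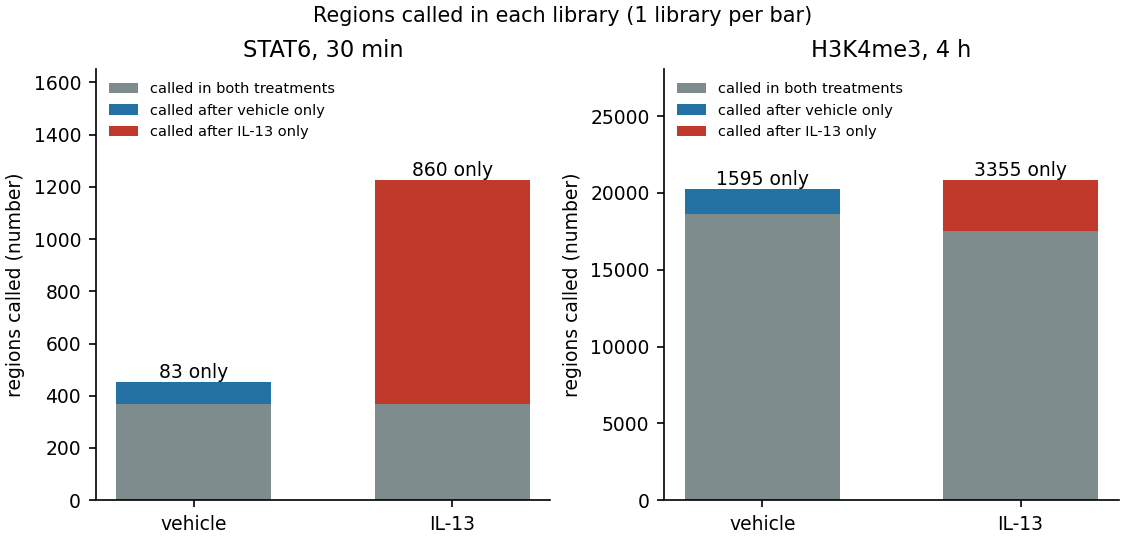
Number of called regions (vertical axis) per library, for STAT6 at 30 min (left) and H3K4me3 at 4 h (right), with regions that overlap a region of the other treatment in grey and the others in color. STAT6 had 860 IL-13-only and 83 vehicle-only regions, and H3K4me3 had 3355 and 1595.

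The 10 IL-13-only STAT6 regions with the highest fold enrichment were 603 to 1158 bp wide, had summits of 28 to 63 tags and touched no H3K4me3 region of either treatment. The highest lay on chromosome 4 at 11701788 to 11702912, with a fold enrichment of 43.3, and its nearest H3K4me3 region was 269.9 kb away. It was followed by a region on chromosome 15 at 38904213 to 38905088 with a fold enrichment of 24.4, and by one on chromosome 6 at 110830846 to 110831763 with 23.7. Regions on chromosome 17 at 57863657 to 57864511 and on chromosome 5 at 131725158 to 131725859 both reached 22.3. Next came chromosome 1 at 234668747 to 234669349 and chromosome 6 at 105984504 to 105985471, both with 21.0. The remaining members were chromosome 3 at 50638286 to 50639443 and chromosome 9 at 117929055 to 117929865, both with 20.3, and chromosome 5 at 167185921 to 167186978 with 19.6. The region on chromosome 3 was the closest of the 10 to an H3K4me3 region, at 8.12 kb.

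Regions of STAT6 called under both treatments had another distribution. They numbered 368 in the IL-13 list and 369 in the vehicle list, and 278 of the 369 (75.3%, interval 70.7 to 79.5%) had at least 5 other shared regions within 1 Mb, whereas 13.4% (11.3 to 15.8%) of the IL-13-only regions had as many other IL-13-only regions in that range. On chromosomes 1 to 22 and X, the groups with the most shared regions, joined over gaps of up to 1 Mb, held 50 regions on chromosome 16 between 46.39 and 46.44 Mb, 37 on chromosome 10 between 42.36 and 42.60 Mb and 33 on chromosome 4 between 49.09 and 49.66 Mb. Of the 83 vehicle-only regions, 56 (67.5%, 56.8 to 76.6%) overlapped an H3K4me3 region. The 6 with the highest fold enrichment (9.73 to 12.7, a tie included) were 164 to 215 bp wide. They lay on chromosome X at 61712550, chromosome 4 at 49149257, chromosome 6 at 58773779, chromosome 2 at 90381304, chromosome 1 at 121386203 and chromosome 14 at 106235712. In 5 of these 6, the one on chromosome 14 being the exception, H3K4me3 regions of both treatments overlapped the STAT6 region.

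**Figure D2:**
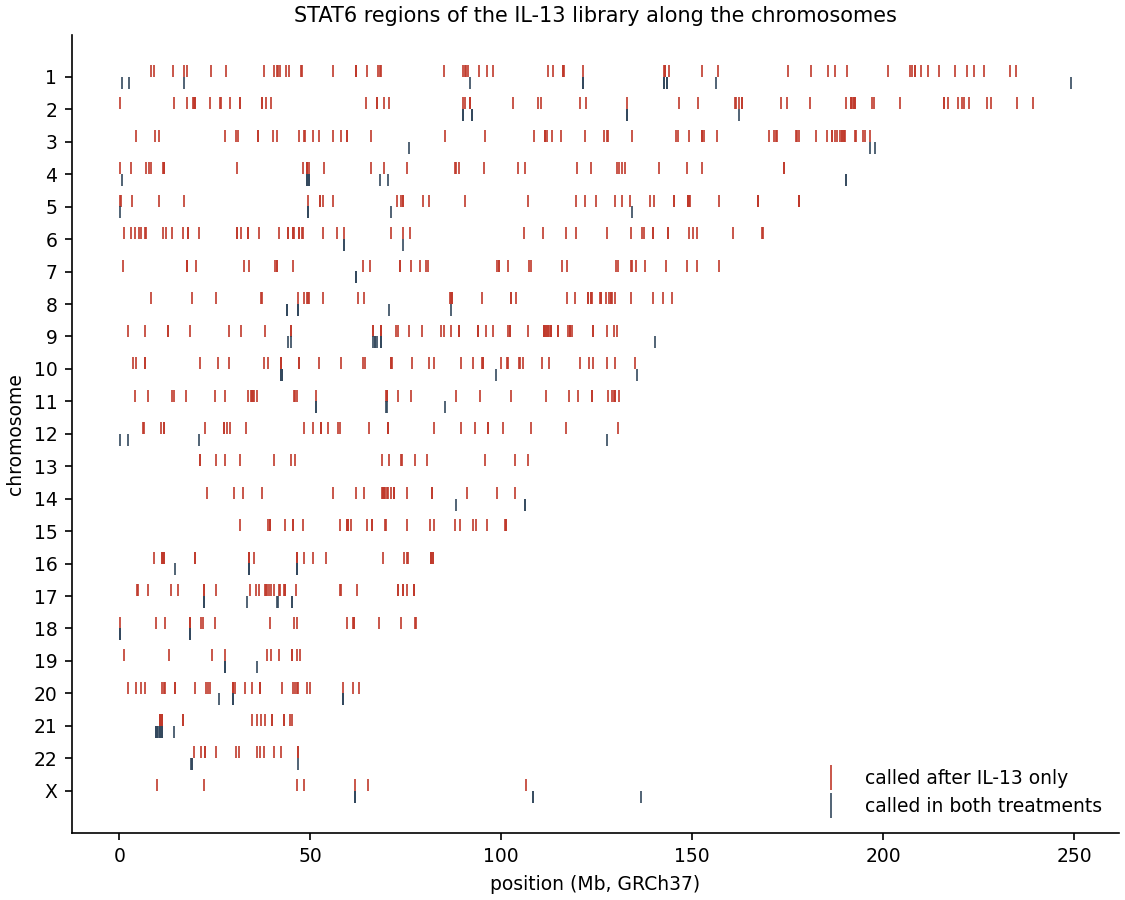
Position in Mb (horizontal axis) of each STAT6 region of the IL-13 library on chromosomes 1 to 22 and X (vertical axis). Red ticks mark IL-13-only regions, which are spread along the chromosomes. Dark ticks below them mark regions also called after vehicle, which crowd at few places, such as 50 regions near 46.4 Mb on chromosome 16.

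STAT6 regions were then compared with H3K4me3 regions, to see whether STAT6 was called where H3K4me3 was called. Both were called without a control library, so an overlap can also come from signal that does not depend on the antibody. It does not by itself place STAT6 at a promoter. Of the 860 IL-13-only STAT6 regions, 97 (11.3%, interval 9.33 to 13.6%) overlapped an H3K4me3 region of either treatment. Regions of the same widths at random positions on the same chromosomes gave a mean of 0.908% over 100 draws, with a highest draw of 1.98%. The share was 94.3% (91.4 to 96.2%) for the shared STAT6 regions. Of the 750 IL-13-only regions more than 100 kb from any vehicle STAT6 region, 29 (3.87%, 2.71 to 5.50%) overlapped an H3K4me3 region, against a mean of 0.997% and a highest draw of 2.00% at random positions. These 750 regions were a median of 49.1 kb from the nearest H3K4me3 region, with quartiles of 15.5 and 119.9 kb, compared with a mean of the random medians of 116.3 kb. Within 10 kb of an H3K4me3 region lay 143 of them (19.1%, 16.4 to 22.0%), against 10.1% at random positions.

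**Figure D3:**
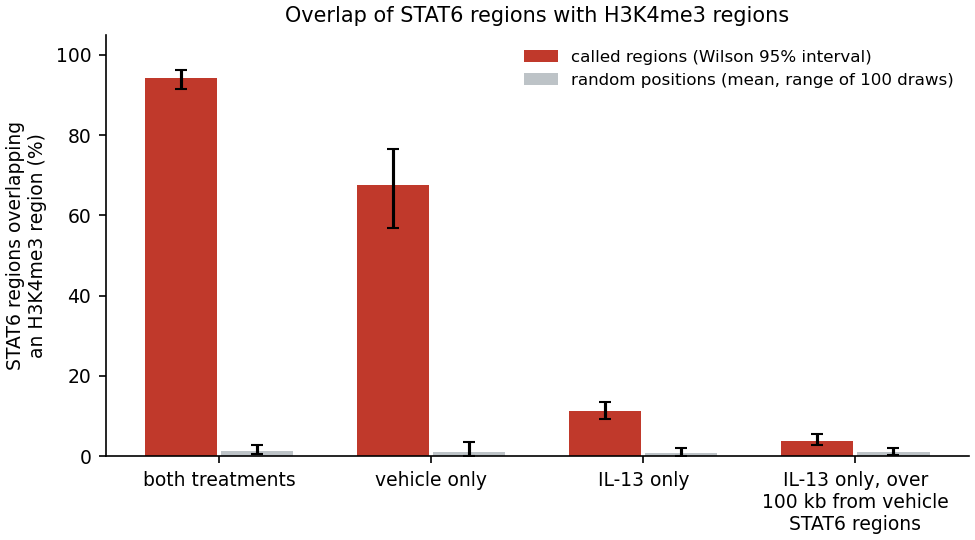
Percent of STAT6 regions that overlap an H3K4me3 region of either treatment (vertical axis), by the treatments in which the STAT6 region was called (horizontal axis). Red bars are called regions with Wilson 95% intervals, at 94.3% for regions of both treatments and 11.3% for IL-13-only regions; grey bars are random positions, with the mean and range of 100 draws.

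The second comparison asked which regions carried H3K4me3 after 4 h of IL-13. The vehicle library had 20248 H3K4me3 regions covering 18.9 Mb and the IL-13 library 20872 regions covering 20.7 Mb. Most were common to both treatments, at 17517 of the IL-13 regions (83.9%, interval 83.4 to 84.4%) and 18653 of the vehicle regions (92.1%, 91.7 to 92.5%). The 3355 IL-13-only and 1595 vehicle-only regions were weak, with median summits of 6 and 5 tags, compared with 27 and 20 tags in the shared regions of the same lists. No IL-13-only summit exceeded 16 tags and no vehicle-only summit exceeded 12. Many adjoined a region of the other treatment, since 1992 of the IL-13-only regions (59.4%, 57.7 to 61.0%) and 1025 of the vehicle-only regions (64.3%, 61.9 to 66.6%) lay within 1 kb of one. The counts of treatment-specific H3K4me3 regions depended on the threshold. With a −log10 q-value of at least 5 required in both lists before the overlap, there were 1156 IL-13-only and 1073 vehicle-only regions. These counts also take in regions whose partner in the other list fell below the limit. Of the 3355 and 1595 regions themselves, 555 and 361 reached the limit.

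By the rule of highest fold enrichment, 12 IL-13-only H3K4me3 regions were singled out, with fold enrichments of 10.1 to 11.4 and a tie at the lower end. In 9 of the 12, a vehicle H3K4me3 region lay within 1 kb. These 9 began on chromosome 1 at 85462493, 143914052 and 162760854, on chromosome 2 at 241500737, on chromosome 3 at 135684095, on chromosome 5 at 10307729 and 177302625, on chromosome 19 at 46273582 and on chromosome X at 46433174. The other 3 stood alone. They lay on chromosome 9 at 10642 to 10897, 17.95 kb from the nearest vehicle H3K4me3 region, on chromosome 11 at 114167224 to 114167925, 102.4 kb away, and on chromosome 11 at 69924254 to 69925492, 123.5 kb away. The last was 1239 bp wide with 3 summits, the widest of the 12. An IL-13 STAT6 region lay within 50 kb of 2 of the 12, the region on chromosome 11 at 69924254 and the region on chromosome X at 46433174. Among vehicle-only H3K4me3 regions the 10 highest had fold enrichments of 8.30 to 8.99, the first 2 beginning on chromosome 1 at 43751022 and on chromosome 17 at 22254738. In 5 of these 10, the one on chromosome 17 included, an IL-13 H3K4me3 region lay within 1 kb.

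The series' gene of interest, ANO1, is a chromosome 11 gene in the RefSeq table, and whether any region below belongs to it was not analysed here. The IL-13 regions of STAT6 were joined into loci over gaps of up to 50 kb, and 646 of the 756 loci on chromosomes 1 to 22, X and the mitochondrial genome held no region that touched H3K4me3. The locus on chromosome 11 from 69909488 to 70035341 held 9 STAT6 regions, 7 of them IL-13-only, within 125.9 kb, the most among these 646 loci, and the locus with the next most held 4 IL-13-only regions, on chromosome 9 from 117929055 to 117969728. Among all 756 loci it came after one on chromosome 21 from 11079127 to 11186722, with 14 IL-13-only regions among 17, of which 5 touched H3K4me3. Of the 646 loci in which no STAT6 region touched H3K4me3, 564 held 1 IL-13-only region. The 7 IL-13-only regions of the chromosome 11 locus had summits of 6 to 23 tags, and 5 of them had a −log10 q-value of at least 5. The highest lay at 69909488 to 69909962 with a fold enrichment of 16.2, which was 14.3 kb from the IL-13-only H3K4me3 region at 69924254 to 69925492 inside the locus. The other 2 STAT6 regions were also called after vehicle, and the nearer of them was the STAT6 region closest to that H3K4me3 region, at 8.42 kb. At 69933915 to 69934199 the summit was 19 tags after IL-13 and 9 tags after vehicle, and at 70033833 to 70035341 it was 26 and 11 tags. An H3K4me3 region at 70048978 to 70050844 was called in both treatments, with summits of 33 tags after IL-13 and 32 after vehicle. This ranking of loci was chosen after the values were seen.

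**Figure D4:**
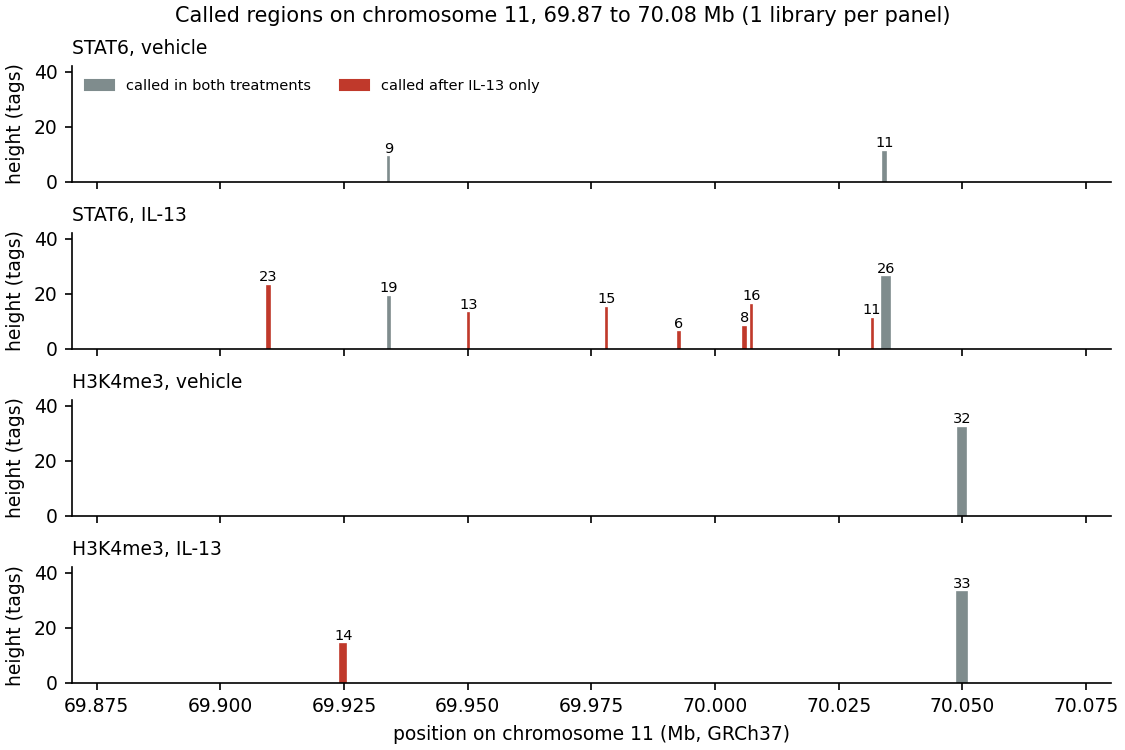
Called regions between 69.87 and 70.08 Mb on chromosome 11 (horizontal axis, GRCh37) in the 4 libraries, each drawn to scale with its summit height in tags (vertical axis, not scaled for depth). Red marks regions called after IL-13 only, 7 for STAT6 and 1 for H3K4me3, and grey marks regions called in both treatments.

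The last comparison asked whether H3K4me3 regions called after IL-13 only lay near STAT6 regions called after IL-13 only. Within 10 kb of an IL-13-only STAT6 region were 152 of the 3355 IL-13-only H3K4me3 regions (4.53%, interval 3.88 to 5.29%), 154 of the 1595 vehicle-only regions (9.66%, 8.30 to 11.2%) and 488 of the 17517 shared regions (2.79%, 2.55 to 3.04%). Proximity was thus more frequent for vehicle-only than for IL-13-only H3K4me3 regions. Without regions within 100 kb of a vehicle STAT6 region, a filter chosen after the values were seen, the shares were 1.73% (1.33 to 2.25%), 2.19% (1.54 to 3.11%) and 1.08% (0.935 to 1.25%), and the intervals of the IL-13-only and vehicle-only regions overlapped. That filter also leaves out the chromosome 11 locus, which holds 2 vehicle STAT6 regions. Pairs of IL-13-only STAT6 and IL-13-only H3K4me3 regions left by the filter included chromosome 6, where an H3K4me3 region at 48078581 to 48078875 overlapped a STAT6 region at 48078601 to 48079509 with a fold enrichment of 15.6, and chromosome X, where the H3K4me3 region at 46433174 to 46433897 was 6.56 kb from a STAT6 region at 46426464 to 46426610 with a fold enrichment of 6.77. On chromosome 6 an H3K4me3 region called in both treatments adjoined the pair. On chromosome X a vehicle H3K4me3 region lay 0.009 kb from the H3K4me3 region of the pair, and the STAT6 summit was 9 tags.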

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

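The alternatives with a −log10 q of at least 5, reciprocal overlap and a 1 kb gap were planned; the others were chosen after seeing the data. Of 33 alternatives to 6 results, 16 stayed within 1.5 times the count or within the interval of the percent, and 17 moved further; where no cause is named, the cause was not tested. STAT6 IL-13-only regions outnumbered vehicle-only regions 7.06 to 16.6 times in every setting that gave both counts. With −log10 q of at least 5 in both lists, fewer regions entered: 546 IL-13-only and 50 vehicle-only for STAT6 and 1156 IL-13-only for H3K4me3. With that limit in the counted list alone, the counts were 531 and 38 for STAT6 and 555 and 361 for H3K4me3. Reciprocal overlap of 50% gave 128 STAT6 vehicle-only regions and, for H3K4me3, 6210 IL-13-only and 5586 vehicle-only regions. A 1 kb gap left 49 STAT6 vehicle-only regions and, for H3K4me3, 1363 and 570. The ratio of IL-13-only to vehicle-only H3K4me3 regions thus ranged from 1.08 to 2.39. IL-13-only STAT6 regions in H3K4me3 moved to 15.7% with a 1 kb gap and 3.87% without regions within 100 kb of a vehicle STAT6 region. STAT6 near IL-13-only H3K4me3 regions moved to 9.12% at 50 kb and 1.73% without those regions. All 10 named IL-13-only STAT6 regions were IL-13-only under each planned setting. The closest of them to a vehicle STAT6 region was 2533.9 kb away, and their lowest −log10 q was 35.6. No planned setting could therefore change their status. With a 1 kb gap, 3 of the 12 named IL-13-only H3K4me3 regions stayed IL-13-only. Planned results on transcription starts, promoters, gene lists and the motif, with their alternatives, were not run, because no genome or annotation of the build was used. Depth limits each list at its lowest called height, where the STAT6 lists had 14 vehicle and 59 IL-13 regions and the H3K4me3 lists 741 and 740. No paired analysis was possible because each group had 1 library.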

Other observations

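The tests of sequencing depth and of antibody-independent signal on the STAT6 regions called after IL-13 only, and of shared STAT6 regions missed in the vehicle H3K4me3 library, and the comparisons of widths, were chosen after the results were seen; the other tests below were written down before their results were seen.

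Loci with several IL-13-only STAT6 regions, none touching H3K4me3, were found beyond chromosome 11, by a ranking chosen after the values were seen. A total of 12 of the 646 loci without a STAT6 region that touched H3K4me3 held 3 or more IL-13-only regions. They included 4 regions over 40.7 kb on chromosome 9 from 117929055 to 117969728 and 3 regions over 27.2 kb on chromosome 17 from 77007656 to 77034897, where the highest fold enrichment was 15.6. Widths of H3K4me3 regions also differed between the libraries. Among 13338 regions that matched 1 to 1, 66.9% (Wilson 95% interval 66.1 to 67.7%) were wider after IL-13, with medians of 1036 bp after IL-13 and 959 bp after vehicle. Regions at least 3000 bp wide numbered 339 after IL-13 and 214 after vehicle. The IL-13 library was 1.10 times deeper, which can widen regions at a constant height limit. Heights divided by filtered tags were also a median of 1.12 times higher after IL-13 in the matched regions. Whether depth or height accounts for the widths was not tested.

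STAT6 was called at 860 regions after IL-13 only and at 83 after vehicle only. The values argued against greater depth of the IL-13 library as the whole cause, since 3.87 times as many IL-13 regions were missed after vehicle as Poisson counting gave at equal tag rates. That count took called heights as true rates, which makes the expected number too low for regions near the limit. Among the 349 regions whose height would be at least 10 tags at the vehicle depth, 100 were missed, against 1.39 expected. Signal enriched whatever the antibody was also argued against as the whole cause. Of the IL-13-only regions, 5.93% touched regions of both H3K4me3 lists, compared with 89.9% of the shared STAT6 regions. The shared regions had higher summits, with a median of 20 against 9 tags in the IL-13 list, which eases calling in further libraries. Of the 83 vehicle-only STAT6 regions, with a median summit of 7 tags, 47.0% (36.6 to 57.6%) touched both lists. Such signal stays open for the 110 IL-13-only regions within 100 kb of a vehicle STAT6 region. Of these, 33.6% (Wilson 95% interval 25.5 to 42.9%) touched both lists and 61.8% touched either. The 110 include the 7 IL-13-only regions of the chromosome 11 locus, none of which touched H3K4me3. A hypothesis is therefore that most of the 750 other IL-13-only regions may reflect STAT6 brought to chromatin by IL-13. A difference between these 2 libraries in immunoprecipitation yield stays open, since there was 1 library per treatment, and in the 368 shared regions the height divided by filtered tags after IL-13 was a median of 0.821 times that after vehicle.

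Most STAT6 regions called under both treatments may be signal that does not depend on the antibody. In the 335 of 369 that touched a vehicle H3K4me3 region, summit heights divided by the library's filtered tags were close for both antibodies, with a median log2 ratio of H3K4me3 to STAT6 of 0.19 and quartiles of −0.24 and 0.44. The other 34 touched no vehicle H3K4me3 region. Poisson counting at equal tag rates would miss 1.62 regions in the vehicle H3K4me3 library, giving an observed number 21.0 times the expected one. Equal tag rates in the STAT6 and H3K4me3 libraries thus do not account for all 34, although regions were counted as independent and some lie side by side. The STAT6 and H3K4me3 libraries also differed in time and in chromatin amount. The excess therefore cannot decide whether the signal in these 34 regions depends on the antibody. Signal particular to the STAT6 libraries cannot be told apart from STAT6 binding there. Of the 34, 21 were in neither H3K4me3 list. These 21 included 2 of the 5 shared regions with the highest fold enrichment and the 2 shared regions of the chromosome 11 locus. The former lay on chromosome 20 at 58563884 to 58564290, with 206 tags after IL-13 and 215 after vehicle, and on chromosome 14 at 106207825 to 106208636, with 199 and 212 tags. These counts are not scaled for depth, and the STAT6 library after IL-13 had 1.42 times as many filtered tags. The chromosome 20 region belonged to a group of 9 shared regions between 58.55 and 58.57 Mb. In the 2 shared regions of the chromosome 11 locus, summits were 19 and 26 tags after IL-13 and 9 and 11 after vehicle. STAT6 held at H3K4me3-marked promoters without IL-13 was argued against as the main source, since 75.3% of the shared regions had at least 5 others within 1 Mb, compared with a mean of 0.225% for equally many vehicle H3K4me3 regions drawn at random.

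H3K4me3 was called at 3355 regions after IL-13 only and at 1595 after vehicle only. Thinning the IL-13 summits to the vehicle depth left a ratio of 1.86 (counting SD 0.057), which argued against depth and counting noise as the whole cause. Without thinning, however, the ratio was 1.08 with a −log10 q of at least 5 in both lists, and 1.54 with that limit in the counted list alone. The same tag height gives a different −log10 q in each list, such as 10.1 after IL-13 and 10.5 after vehicle at 11 tags. How far this lowers the ratio was not tested. Heights divided by filtered tags were also higher after IL-13, by a median of 1.12 times in regions matched 1 to 1. Thinning by that factor as well left a ratio of 1.52 (counting SD 0.046), too close to the bound of 1.5 set in advance to decide. Whether generally higher heights are the cause cannot be told apart from IL-13 itself, since each treatment had 1 library.

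A further hypothesis was that H3K4me3 is higher after IL-13 near regions where STAT6 was called after IL-13 only. Among matched H3K4me3 regions more than 100 kb from vehicle STAT6 regions, the 481 within 50 kb of an IL-13-only STAT6 region had a median log2 ratio of tag-scaled height, IL-13 over vehicle, of 0.18. The medians of 10000 random sets matched on mean height lay between 0.12 and 0.20 in their central 95%, so no general shift was detectable. Single regions went both ways. On chromosome 14 at 23057324 to 23058767 the summit was 52 tags after IL-13 and 19 after vehicle, 23.7 kb from an IL-13-only STAT6 region. On chromosome 5 at 131746040 to 131747014 it was 13 and 28 tags, 20.2 kb from the STAT6 region at 131725158, one of the 10 highest. A share of 73.4% (69.3 to 77.1%) of the 481 regions was wider after IL-13, compared with 67.6% (66.8 to 68.4%) of the 12297 other regions. The other regions were not matched on height here, so these shares cannot link the wider regions to STAT6.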
